A study of Homo sapiens and Mus musculus with 17 samples.

How the data were processed

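RNA of 9 K562 libraries (3 parental, 3 sgHsf2, 3 sgHsp110) and 8 mouse libraries labelled marrow had been sequenced. The mouse labels give wild type or Hsf2 knockout, unirradiated or given 250 rad, with 2 libraries per group. Per the labels, the authors used FastQC 0.11.8, STAR and DESeq2 with the genome builds hg38 and mm10; other versions are not given in the sources used here. For K562 the authors deposited 1 table of raw counts per gene. For mouse the authors deposited tables with 1 line per transcript model that hold raw counts, a fold (ratio) of wild type over knockout and a p-value. Checked on the files, the authors' fold is the ratio of summed raw counts in 21205 of 21205 unirradiated and 22631 of 22631 irradiated lines, and the authors' p-value is a Welch test of raw counts in 22722 of 22722 and 24057 of 24057. The sort is labelled lineage-negative and Kit-positive, with Sca1 added in 1 label field, and the time after irradiation is not given in the sources used here.

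The K562 table has 60654 lines, of which 60652 were read; 2 hold no counts, and 1 of these names a gene. The 63759 mouse lines were summed per gene symbol to 32754 features, where 82 lines whose symbol had turned into a date were kept as features of their own. Genes with several transcript lines have lower counts in this table: among genes abundant in K562, the median CPM in the libraries labelled irradiated was 106 for genes with 1 line, 4.91 with 2 and 1.16 with 3 or more. Genes with 1 line hold 81.03% of mouse counts. K562 libraries hold 191149261 to 254723464 counts and 30726 to 32847 detected features, and mouse libraries 8563656 to 19692688 counts and 13666 to 15861 features. The 50 most abundant genes take 13.6 to 15.0% of K562 counts, 55.6 to 62.8% in the libraries labelled unirradiated and 26.0 to 29.4% in those labelled irradiated. Replicates differed beyond counting error (chi-square per degree of freedom from 7.51 in K562 and from 35.44 in mouse), so no library is a copy of another of its group; pairs across groups were not compared.

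Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15), TMM scaling, a robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. All 9 K562 libraries shared 1 fit and all 8 mouse libraries another, with 1 coefficient per group. The 3 K562 contrasts, the knockout label within each radiation label, the radiation label within each genotype label, their interaction, and each factor adjusted for the other were tested. CPM values are after TMM scaling, as mean ± SD, and log2 fold changes carry the SE of the fit. Intervals and floors built from counts cover counting error only. A gene at 0 counts in a whole group was compared with a floor of 3 counts per library.

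Genes named in the report are drawn from the targeted genes and their families, the 10 largest changes per direction, and members of gene lists. The largest changes were taken among genes with an adjusted p under 0.05 and at least 5 CPM in the higher group. Except for the interaction, the replicates of the groups compared also had to be apart in CPM. The lists were heat-shock chaperones, the HSP110 family, heat shock factors, core spliceosome, SR and hnRNP splicing regulators, DNA repair, p53 targets, cell cycle, apoptosis, interferon response, Notch and T-cell leukemia genes, unfolded-protein response, immediate early genes, cytosolic ribosomal proteins, mitochondrially encoded genes, stem and progenitor cells, and markers of erythroid, megakaryocyte, neutrophil, monocyte, B, T and NK, mast and basophil and stromal cells, with globins for human and sex-linked and Hsf2-flanking genes for mouse. Lists of adipocyte and skeletal-muscle genes were added after the data were seen. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 (preset correlation 0.01), and again with an estimated correlation, with the rotation test fry and with replicate as a block.

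Comparisons, tests, lists and most alternatives were chosen before the data were examined. The alternatives were no low-count filter, a stricter filter (50 counts), RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, replicate number as a block, a fit of only the groups compared, a minimum log2 fold change of 1, and leaving out each library in turn. Scaling by library size only and a fit of mouse genes with 1 line were added after the data were seen. The edgeR step was tested on simulated data, with 50 genes changed at each of 1.5, 2, 4 and 8-fold. Each gene had its mean level over all libraries of its table, so the simulated mouse libraries did not differ by radiation label. In the sgHsf2 design it recovered 52, 74, 92 and 96%, and 9 unchanged genes were called. Within the libraries labelled unirradiated it recovered 0, 0, 26 and 60%. Gene positions are on GRCh38. Windows of 10 Mb with at least 20 tested genes were compared with 1000 shuffles of the genes. Splicing and sequence reads are not analysed here.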

Results

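The series compares RNA from human K562 cells and from mouse samples labelled bone marrow by RNA sequencing. K562 is an erythroleukemia cell line. Its 9 libraries form 3 groups of 3: parental cells, sgHsf2 cells and sgHsp110 cells, where sg stands for the single guide RNA that directs the Cas9 nuclease to a gene. HSF2 encodes heat shock factor 2, a transcription factor, and Hsp110 is the protein of HSPH1, a large chaperone that works with HSP70. The 8 mouse libraries are labelled lineage-negative, Kit-positive marrow cells of wild-type or Hsf2 knockout mice, unirradiated or given 250 rad, with 2 libraries per group. K562 libraries hold 191149261 to 254723464 counts and mouse libraries 8563656 to 19692688. All values are gene totals, so splicing is not analysed here. The labels do not say whether replicates are separate cultures or animals, so the p-values measure a spread between samples that may be technical.

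The first question is which transcripts differ in sgHsf2 cells. HSF2 (ENSG00000025156, chromosome 6, 122399551 to 122433119, plus strand, GRCh38) fell from 44.5 ± 1.38 CPM (counts-per-million after scaling, mean ± SD, n = 3) in parental cells to 14.9 ± 0.586, a 2.98-fold fall (log2 fold change -1.58 ± 0.04 SE, adjusted p = 3.91e-16). HSPH1 (ENSG00000120694, chromosome 13, 31134973 to 31162388, minus strand) fell too, from 443 ± 4.91 to 256 ± 11.2 CPM (-0.79 ± 0.04, adjusted p = 7.82e-12). Its relative HSPA4 (ENSG00000170606) fell by 0.15 (adjusted p = 0.0022), HSPA4L (ENSG00000164070) rose by 0.13 (adjusted p = 0.0338), and HSF1 (ENSG00000185122), the other main heat shock factor, did not pass the test (0.02 ± 0.04, adjusted p = 0.751). HSF2, HSPH1 and HSPA4 were lower and HSPA4L higher in 3 of 3 sgHsf2 libraries than in any parental library. The HSPA4L call is lost without parental replicate 2 or 3 (adjusted p = 0.087 and 0.103) or sgHsf2 replicate 2 or 3 (0.101 and 0.107), and also with replicate as a block (0.0501), upper-quartile scaling (0.0605) or library size only (0.16). Counts of RNA show neither the edit nor the protein.

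**Figure D1:**
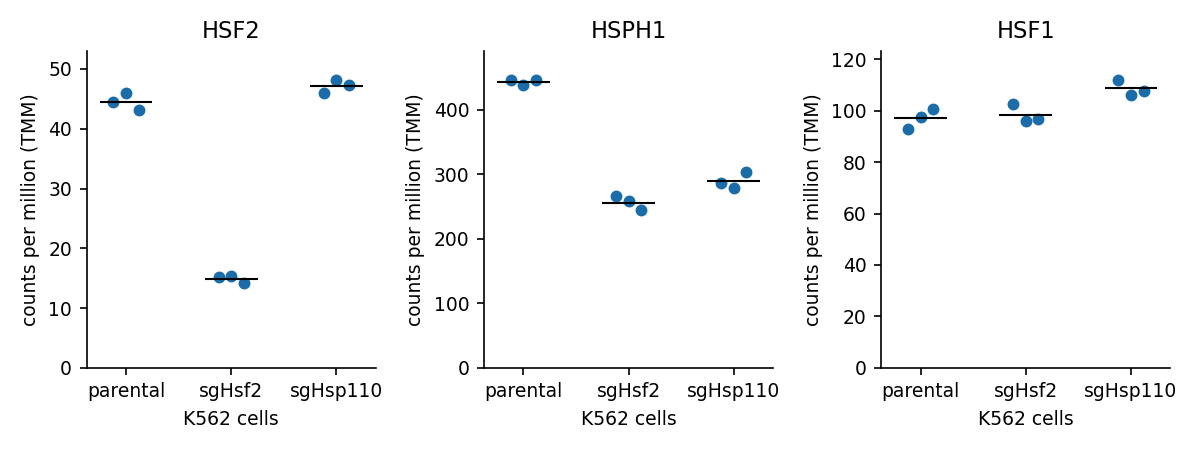
HSF2, HSPH1 and HSF1 in each K562 library. Points are libraries and lines are group means.

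The largest rises in sgHsf2 cells are given here for genes that reach 5 CPM in the higher group. PTPRC (ENSG00000081237), the leukocyte antigen CD45, rose from 0.347 ± 0.0456 to 8.87 ± 0.484 CPM (4.67 ± 0.12, adjusted p = 1.48e-16). COL5A1 (ENSG00000130635), a collagen chain, rose from 1.6 ± 0.141 to 36.2 ± 1.56 (4.50 ± 0.08), the adhesion receptor CD44 (ENSG00000026508) from 0.89 ± 0.102 to 19.3 ± 4.09 (4.44 ± 0.20), and the chemokine CXCL8 (ENSG00000169429) from 2.19 ± 0.675 to 40.1 ± 0.858 (4.18 ± 0.20). GABRG3, EPHB6, TEX11, SCIN, CCDC26 and HDAC9 rose by 3.26 to 3.63. The largest falls were in CPVL (ENSG00000106066), a carboxypeptidase, from 11.3 ± 0.458 to 0.0316 ± 0.0122 CPM (-8.46 ± 0.16, adjusted p = 4.27e-19), the kinase SYK (ENSG00000165025), from 5.41 ± 0.674 to 0.091 ± 0.0383 (-5.86 ± 0.21), and AFF3 (ENSG00000144218, -4.84 ± 0.15). PAPPA, MAGEA1, CTDSPL, WDR72, CHRM3 and ZNF331 fell, with log2 fold changes from -2.95 to -2.28. These genes were picked among those whose replicates do not overlap between the groups. That each lay outside the parental range in 3 of 3 sgHsf2 libraries follows from this choice.

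Chaperone genes mostly fell in sgHsf2 cells. Of 42 heat-shock chaperone genes, 6 rose and 23 fell (6 and 25 adjusted over the list alone). HSP90AA1, the inducible HSP90, fell by 0.82 (± 0.04, adjusted p = 5.25e-13), and HSPA1A, the inducible HSP70, from 146 ± 0.536 to 84.3 ± 7.16 CPM (-0.80 ± 0.05), while HSPB1 rose by 0.49. CRYAB, on chromosome 11, rose by 1.17. The camera test called the list lower (adjusted p = 5.92e-05, but adjusted p = 0.567 with an estimated correlation). Of the 4 genes of the HSP110 family list, 2 rose and 2 fell, and of 5 heat shock factor genes 1 rose and 3 fell (camera adjusted p = 0.0744).

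Of 79 core spliceosome genes in sgHsf2 cells, 16 rose (15 adjusted over the list alone) and the rest did not pass the test; 5 of the 16, SART1 (0.51) and CWC15 (0.46) among them, lie on chromosome 11. With library size only the split was 14 higher and 4 lower (camera adjusted p = 0.0425, 0.718 with an estimated correlation). Among 60 SR and hnRNP splicing regulators 9 rose, such as HNRNPLL (0.44), and 8 fell, such as MBNL3 (-2.97); with RLE or upper-quartile scaling, DESeq2 or limma-voom falls outnumbered rises, and with library size only 7 rose and 25 fell (camera adjusted p = 0.287). Cytosolic ribosomal protein genes rose in 59 of 76 cases, 6 of them on chromosome 11, where RPL27A rose by 0.76 and RPS13 by 0.72 (camera adjusted p = 2.27e-12, 0.401 with an estimated correlation). All 12 mitochondrially encoded genes that passed, of 13, fell, with MT-CYB at -0.57 and MT-ND2 at -0.46 (camera adjusted p = 1.18e-06, 0.381 with an estimated correlation).

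Among blood-lineage genes of sgHsf2 cells, the erythroid list held mostly falls. Of 41 erythroid genes 1 rose and 26 fell (2 and 28 adjusted over the list alone), and 4 of 8 globin genes fell: HBA2 went from 10.8 ± 1.52 to 3.6 ± 0.309 CPM (-1.59 ± 0.09, adjusted p = 5.34e-11), and HBD fell by 1.18 although it lies on chromosome 11. Camera gave adjusted p = 7.87e-10 for the erythroid list and 7.44e-05 for the globins, and 0.329 for each with an estimated correlation. In the megakaryocyte list 9 of 16 genes rose and 2 fell; THBS1, a platelet granule protein, rose from 24.3 ± 0.922 to 65.1 ± 4.27 CPM (1.42 ± 0.05), and CD9 fell by 0.70 (camera adjusted p = 0.0135, 0.322 with an estimated correlation). T and NK cell genes rose in 9 of 16 cases (TRBC1 2.02; camera adjusted p = 0.00148) and stromal genes in 7 of 11 with 1 fall (COL1A2 4.30; adjusted p = 0.00854); each of these gave 0.322 with an estimated correlation. Stem and progenitor genes rose in 8 of 21 cases and fell in 3 (RUNX1T1 1.15; camera adjusted p = 0.0301, 0.381 with an estimated correlation). Among granulocyte and monocyte genes, 4 of 15 neutrophil and 3 of 12 monocyte genes rose and 1 of each fell, with LYZ at 1.90 (adjusted p = 0.182 and 0.287). B cell genes (1 rose, 2 fell, of 11) and mast cell and basophil genes (1 and 3 of 10) gave adjusted p = 0.865 and 0.923, and the mast list has a median below 0 and a mean above it; MS4A3 rose from 315 ± 9.85 to 1030 ± 75.4 CPM, and it lies on chromosome 11.

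Stress, growth and signalling lists held both directions. The AP-1 gene JUN fell from 82.1 ± 2.49 to 27.8 ± 1.21 CPM (-1.56 ± 0.05, adjusted p = 5.35e-16) and JUND by 0.50, while 8 of 23 immediate early genes rose and 7 fell (7 and 8 with library size only; camera adjusted p = 0.864). In the DNA repair list 10 of 89 genes rose and 27 fell (11 and 27 adjusted over the list alone), for example RNF168 at -0.47 (camera adjusted p = 0.127). ATM rose by 0.54, and 6 of the 10 genes that rose lie on chromosome 11. Cell-cycle genes rose in 9 of 53 cases and fell in 20, such as E2F2 (-0.55), with adjusted p = 0.0615. Among 43 p53 targets 14 rose and 8 fell, with PLK2 at 2.90 (adjusted p = 0.287). Unfolded-protein response genes fell in 9 of 36 cases, HERPUD1 by 0.77, and rose in 4 (adjusted p = 0.0744). The split was 10 up and 6 down of 24 for apoptosis genes (BIRC3 1.70, chromosome 11; adjusted p = 0.251), 10 up and 4 down of 32 for interferon genes (IFIH1 1.35; CXCL10 3.58; adjusted p = 0.454, with a median below 0 and a mean above it), and 13 up and 5 down of 36 for Notch and T-cell leukemia genes (TAL1 -0.35; adjusted p = 0.114).

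In all, edgeR called 7188 of 23464 genes, 3931 higher and 3257 lower, of which 870 and 449 changed at least 2-fold. With library size only the split was 3349 higher and 4183 lower. A part of the higher genes lies on 1 chromosome: on chromosome 11, 704 of 1235 tested genes rose and 34 fell, and the median fold was 1.32 (median log2 fold change 0.40, 83.6% of genes higher). Without that chromosome 3227 genes rose and 3223 fell. Each other autosome and X had a median log2 fold change from -0.04 (chromosome 19) to 0.06 (X). The lower quartile on chromosome 11 was 0.16. So broad a rise on 1 chromosome argues against an effect of HSF2 on separate genes as its only cause. For any 1 gene there, a shift of the chromosome cannot be parted here from an effect of HSF2.

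**Figure D2:**
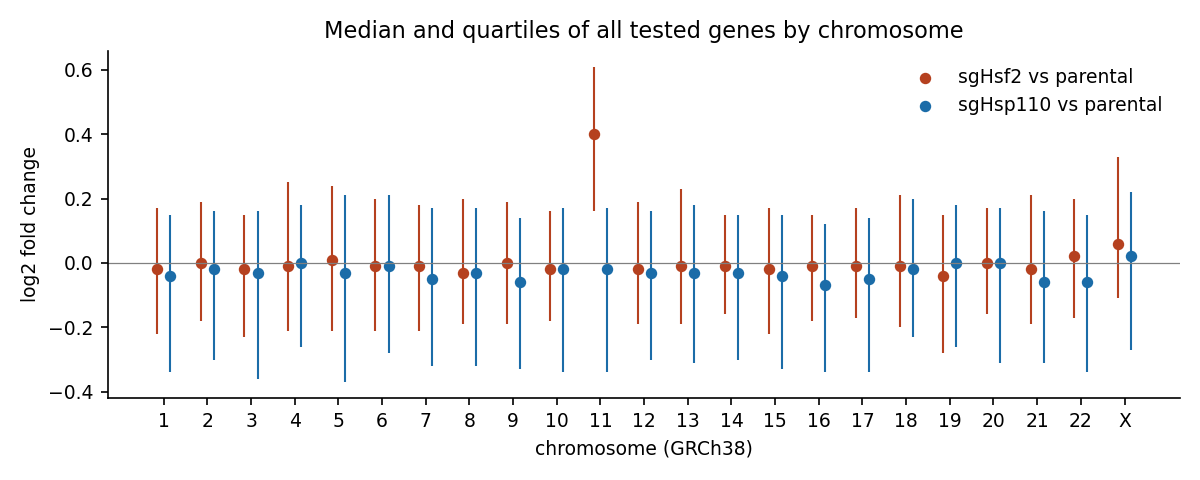
Log2 fold changes of all tested genes by chromosome in sgHsf2 and sgHsp110 cells against parental cells. Points are medians and bars span the quartiles.

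The second question is which transcripts differ in sgHsp110 cells. HSPH1 fell from 443 ± 4.91 to 289 ± 12.8 CPM, a 1.53-fold fall (-0.61 ± 0.04, adjusted p = 1.08e-09), lower in 3 of 3 libraries. HSF2 did not pass the test (0.08 ± 0.04, adjusted p = 0.15), HSPA4 rose by 0.20 (adjusted p = 0.000268), HSF1 by 0.16 (adjusted p = 0.00428, 0.239 with library size only), and HSPA4L did not pass (0.05 ± 0.05). ALDH1A1 (ENSG00000165092), an aldehyde dehydrogenase, rose from 1.77 ± 0.0388 to 26.8 ± 1.19 CPM (3.92 ± 0.07, adjusted p = 5.29e-19), the transcription factor ZNF521 (ENSG00000198795) from 1.15 ± 0.107 to 15.2 ± 0.782 (3.73 ± 0.12), and ADGRG6 (ENSG00000112414) from 1.61 ± 0.0789 to 19.3 ± 0.745 (3.58 ± 0.08). ENAH, an actin regulator, rose by 2.34 and the matrix gene FN1 by 1.86; COBL, EPSTI1, LTB and C3orf80 rose by 1.79 to 2.82. SYK fell from 5.41 ± 0.674 to 0.0428 ± 0.0186 CPM (-6.99 ± 0.24, adjusted p = 3.06e-14) and NDRG1 (ENSG00000104419) from 5.73 ± 0.0606 to 0.745 ± 0.114 (-2.95 ± 0.13). MAGEA1, SLC24A2, DUSP8, AFF3, AFDN, SH3TC1 and UTRN fell, with log2 fold changes from -2.85 to -2.06.

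In sgHsp110 cells 6 lists had more rises than falls and a camera call, which none kept with an estimated correlation. Of 42 heat-shock chaperone genes 30 rose and 4 fell (31 and 5 adjusted over the list alone; 15 and 7 with library size only): the chaperonin subunits TCP1 (0.30) and CCT8 (0.29) rose, and DNAJB4 fell by 0.33 (camera adjusted p = 1.3e-06, 0.519 with an estimated correlation). Core spliceosome genes rose in 62 of 79 cases, SNRNP40 by 0.36 and SNRPE by 0.34; with library size only 31 rose and 2 fell (camera adjusted p = 1.92e-15, 0.44 with an estimated correlation). Among 60 splicing regulators 33 rose (CELF2 0.31) and 3 fell (MBNL3 -2.92), a direction that flips to 13 and 15 with library size only (camera adjusted p = 3.03e-05, 0.519 with an estimated correlation). Ribosomal protein genes rose in 73 of 76 cases (RPS6 0.49; 67 rose with library size only; camera adjusted p = 1.19e-26, 0.44 with an estimated correlation). For DNA repair 37 of 89 genes rose (RAD54L 0.30, RPA2 0.29) and 6 fell, which flips to 15 and 20 with library size only (camera adjusted p = 0.000115, 0.44 with an estimated correlation). Cell-cycle genes rose in 38 of 53 cases, RRM2 by 0.49 and CDC45 by 0.33, and 2 fell; 19 and 7 did with library size only (camera adjusted p = 5.13e-09, 0.44 with an estimated correlation). CCNB1 fell by 0.50; it starts at 69167135 on chromosome 5, in a 10-Mb window whose 70 genes have a median log2 fold change of -0.47.

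In the unfolded-protein response list of sgHsp110 cells 18 of 36 genes fell and 1 rose: DDIT3 went from 13.5 ± 0.855 to 6.71 ± 0.731 CPM (-1.01 ± 0.08) and HERPUD1 from 61.3 ± 4.75 to 32.8 ± 2.01 (-0.90 ± 0.06), with camera adjusted p = 0.000192 (0.519 with an estimated correlation). Immediate early genes fell in 12 of 23 cases and 1 rose; JUN fell by 0.92 and KLF6 by 0.83 (camera adjusted p = 0.000109, 0.44 with an estimated correlation). Mitochondrially encoded genes fell in 9 of 13 cases (MT-CYB -0.34; camera adjusted p = 0.00139, 0.536 with an estimated correlation), and 6 of 16 megakaryocyte genes fell (CLU -0.80, CD9 -0.33; adjusted p = 0.0152, 0.44 with an estimated correlation). Erythroid genes split 10 up and 11 down of 41, or 10 and 9 with RLE scaling or DESeq2 (adjusted p = 0.977; median above 0, mean below). Interferon genes split 11 up and 6 down of 32, Notch and T-cell leukemia genes 11 and 6 of 36, stem and progenitor genes 7 and 3 of 21, apoptosis genes 7 and 6 of 24 and p53 targets 10 and 12 of 43 (camera adjusted p = 0.226, 0.187, 0.27, 0.977 and 0.532). With library size only the first 4 of these had 8 and 7, 6 and 9, 4 and 5, and 4 and 9. The apoptosis split also turned, to 6 and 7, with upper-quartile scaling and with limma-voom. Camera's sign was positive for the apoptosis list, whose median and mean lie below 0, and for the stem list, whose median does.

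In this comparison edgeR called 8124 genes, 4114 higher and 4010 lower, with 278 and 792 at least 2-fold. With library size only the split was 2028 higher and 6544 lower, and the median of all genes moved from -0.029 to -0.138, so the small rises above hold relative to that median.

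**Figure D3:**
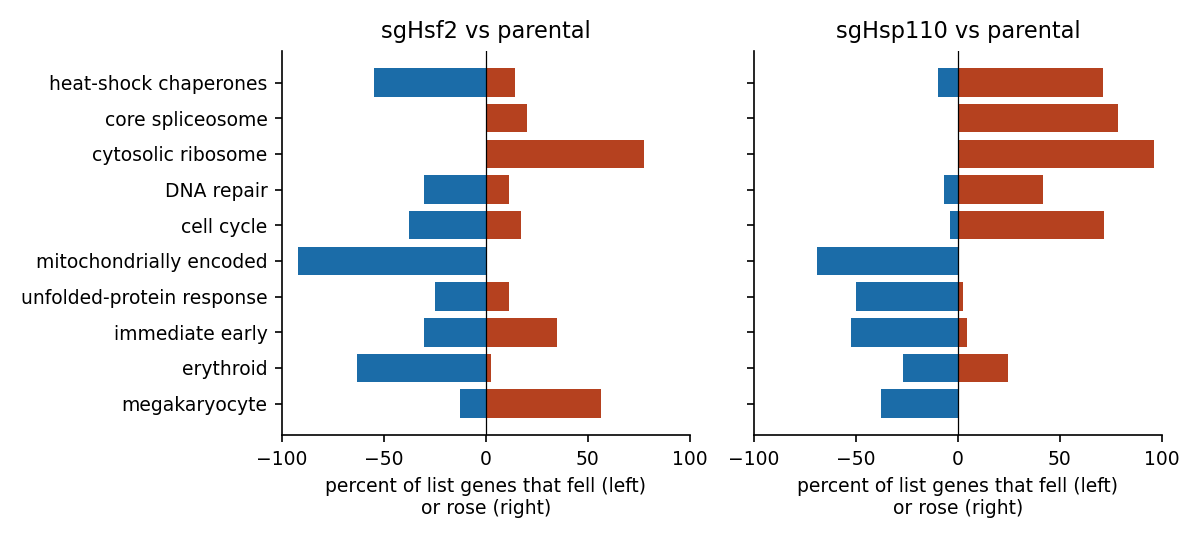
Percent of the genes that rose or fell in the 10 lists drawn, in sgHsf2 and sgHsp110 cells against parental cells. Among the lists drawn, with library size only, the DNA repair direction flips in sgHsp110 cells and the immediate early direction in sgHsf2 cells; erythroid in sgHsp110 cells flips with RLE scaling and DESeq2.

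The next comparison sets the edited lines against each other. HSF2 was higher in sgHsp110 than in sgHsf2 cells (1.66 ± 0.04, adjusted p = 1.02e-16), and so were HSPH1 (0.18, adjusted p = 0.00191), HSPA4 (0.35) and HSF1 (0.14), while HSPA4L did not pass (-0.08, adjusted p = 0.182). Without sgHsp110 replicate 3 HSPA4L passed (adjusted p = 0.0208), and HSF1 did not without sgHsf2 replicate 2 (0.0544) or sgHsp110 replicate 1 (0.0566). With library size only HSPA4L passed (-0.15, adjusted p = 0.0217) and HSF1 did not (0.07, adjusted p = 0.134). CPVL (8.23 ± 0.16), ZNF521 (6.90 ± 0.16), MEST (4.45 ± 0.12) and ENAH (3.94 ± 0.08) were higher in sgHsp110 cells. NBDY (-5.57 ± 0.14), SCIN (-5.43), GABRG3 (-4.81), and MUC15 (-5.03) and CD44 (-4.75) on chromosome 11 were lower. Heat-shock chaperone genes were higher in 32 of 42 cases and lower in 5, HSP90AA1 by 0.84 and HSPA1A by 0.82, and CRYAB was lower (-1.43). Erythroid genes were higher in 26 of 41 cases and lower in 1, with HBA2 at 1.45, and megakaryocyte genes were lower in 11 of 16 and higher in 1, with THBS1 at -1.49. Camera gave adjusted p = 8.04e-10, 4.85e-09 and 1.48e-05 for these 3 lists, and 0.29, 0.22 and 0.138 with an estimated correlation. RAD54L was higher by 0.46 and CCNB1 lower (-0.93). In total 4425 genes were higher and 4890 lower (2922 and 6202 with library size only), 377 and 1391 of them at least 2-fold, and on chromosome 11 the split was 43 higher and 760 lower.

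Many genes moved the same way in both edited lines. SYK, AFF3, MAGEA1, MBNL3, JUN, HERPUD1, CD9 and MT-CYB fell in each. In number, 1413 genes rose in both and 1180 fell in both, against 689.2 and 556.6 expected from independent lists, while 610 rose in sgHsf2 and fell in sgHsp110 cells and 427 did the reverse (671.8 and 571.1 expected). Both comparisons use the same 3 parental libraries, and in 20 simulations of unchanged genes with shared controls at most 0 genes were called up in both and 1 down in both by edgeR. Across genes the log2 fold changes had a covariance of 0.114, against a mean of 0.0401 in the simulations. Their correlation was 0.296 and 62% had the same sign, which is below the 0.501 and 66.6% that shared controls alone gave. The simulations hold no changed genes, and changes of 1 line alone lower both measures. Neither of these 2 measures therefore shows or excludes a shared response. A trait of the parental cultures themselves would appear in both comparisons.

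In the mouse libraries the gene named in the labels is described first. Hsf2 did not pass the test between the libraries labelled knockout and those labelled wild type: 16.3 ± 5.58 against 16.5 ± 7.29 CPM (n = 4 each, log2 fold change 0.07 ± 0.34 adjusted for radiation, adjusted p = 0.965), with 117 to 468 counts under the knockout label and 111 to 336 under the wild-type label. Hsf1 did differ. It had 588 to 736 counts in each library labelled wild type and 2 to 4 in each labelled Hsf2 knockout, lower in 4 of 4 (-8.28 ± 0.51, adjusted p = 0.00048). Pooled over libraries, its level under the knockout label was 0.319% of that under the wild-type label (95% counting interval 0.153 to 0.587%). All Hsf1 counts lie in the same transcript line, and the other Hsf1 lines hold 0 counts in every library. The authors' deposited table gives wild-type over knockout folds of 202 (p = 0.0148) and 331 (p = 0.0711) for Hsf1, and 1.21 (p = 0.797) and 0.515 (p = 0.507) for Hsf2, in the unirradiated and irradiated arms. A knockout allele can leave a transcript that is still counted, so these counts do not show which gene was inactivated.

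**Figure D4:**
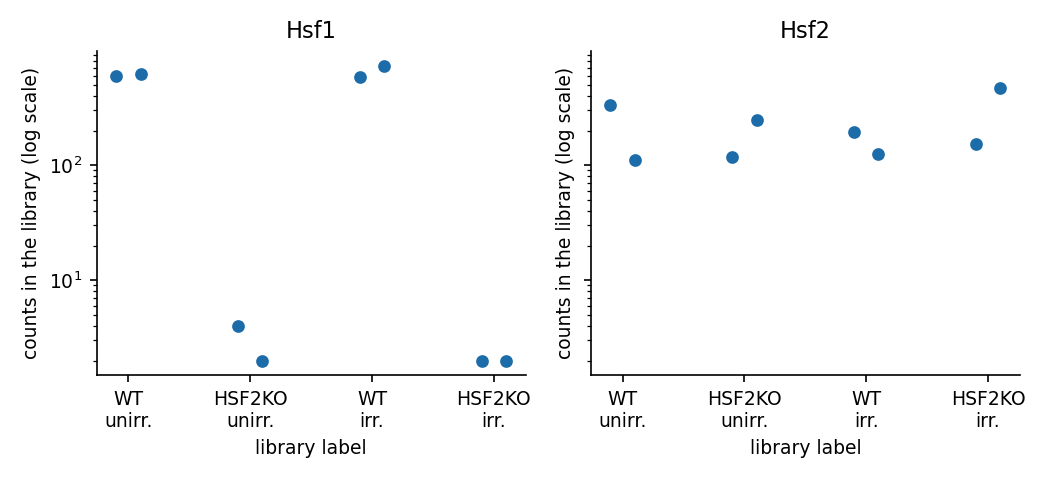
Counts of Hsf1 and Hsf2 in each mouse library by its label.

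Next, marker genes of tissues part the mouse libraries by their radiation label. Ucp1, the uncoupling protein of brown fat, had 54786 to 104055 counts in the libraries labelled unirradiated Hsf2 knockout and 13 to 14 in those labelled irradiated (-13.46 ± 0.53). Cidea, another brown-fat gene, went from 5380 ± 492 CPM in the 4 libraries labelled unirradiated to 0.688 ± 0.332 in the 4 labelled irradiated (-12.99 ± 0.42, adjusted p = 7.78e-08). Plin1 and Kcna5 had 0 counts in each library labelled irradiated, at least 549-fold and 471-fold lower against a floor of 3 counts per library. Myosin and creatine kinase of muscle (Myh4, Ckm) had 1 to 7 and 1 to 5 counts there, against 3978 to 58337 and 1011 to 25050. Genes of blood cells ran the other way. The granule enzyme Mpo rose from 0.758 ± 0.329 to 4310 ± 1750 CPM (12.53 ± 0.56, adjusted p = 2.65e-07) and the mast-cell protease Cpa3 from 3.16 ± 1.4 to 1860 ± 519 (9.19 ± 0.46). Ctsg had 7976 to 15037 counts in the libraries labelled irradiated and 0 to 1 in the others, and the erythroid factor Gata1 4979 to 8014 and 0 to 3. Redrum and Itgb2l had 0 counts in the libraries labelled unirradiated, at least 189-fold and 114-fold higher in the others against the same floor per library. Kit, the gene of the sort label, had 0 counts in each library labelled unirradiated. It had 0 to 5 in those labelled irradiated wild type and 4 to 12 in those labelled irradiated knockout. These Kit counts do not show the labelled sort, and alone they do not speak against it. Genes with several transcript lines have lower counts in this table, which was not tested for Kit.

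**Figure D5:**
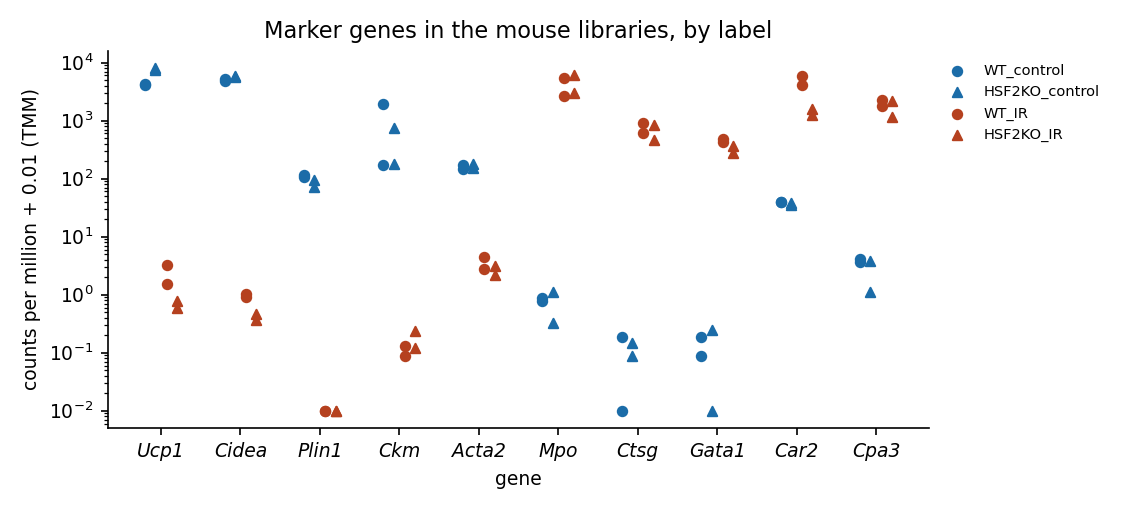
Levels of marker genes in the mouse libraries by label: fat (Ucp1, Cidea, Plin1), muscle (Ckm, Acta2) and blood (Mpo, Ctsg, Gata1, Car2, Cpa3). Points at 0.01 are libraries with 0 counts.

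By list, 23 of 23 adipocyte genes and 11 of 11 skeletal-muscle genes fell in the libraries labelled irradiated (camera adjusted p = 1.93e-12 and 9.77e-05, 0.0943 and 0.342 with an estimated correlation). Adipocyte genes took 14.9 to 17.8% of the counts of each library labelled unirradiated and 0.0668 to 0.091% of the others. In the stromal list 14 of 17 genes fell and 1 rose, Acta2 by -5.70 and Tagln by -4.09 (adjusted p = 9.77e-05). Erythroid genes rose in 25 of 32 cases (adjusted p = 5.08e-07, 0.342 with an estimated correlation), Klf1 from 0.357 ± 0.152 to 411 ± 272 CPM. Of 23 neutrophil genes 21 rose and 2, Cebpa (-3.92) and Hp (-1.04, but 0.10 with library size only), fell (adjusted p = 3.14e-08, 0.342 with an estimated correlation). Monocyte genes rose in 15 of 19 cases with 1 fall (Ly6c2 10.04), mast and basophil genes in 13 of 15 with 1 fall, T and NK genes in 8 of 14, megakaryocyte genes in 12 of 17 with 4 falls, B-cell genes in 5 of 7 with 1 fall, and stem-cell genes in 11 of 21 with 6 falls (Flt3 7.26). Camera gave 0.000766, 0.000135, 0.0163, 0.0508, 0.104 and 0.249 for these 6, and no mouse list kept a call with an estimated correlation.

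Other groups were compared across the same border between labels, and some of them split in both directions. All 41 cell-cycle genes rose, Ccnb2 from 0.476 ± 0.266 to 180 ± 73.8 CPM (8.53 ± 0.38) and Aurkb by 8.47 (camera adjusted p = 1.51e-13). Spliceosome genes rose in 55 of 68 cases with 1 fall (Sf3b3 2.43, Sf3a2 2.09; adjusted p = 8.45e-08), splicing regulators in 25 of 47 with 5 falls (Hnrnpa0 2.03; 0.0207), ribosomal protein genes in 61 of 66 with 2 falls (Rplp0 2.74; 4.37e-11), and DNA repair genes in 40 of 60 with 4 falls (H2afx 4.40, Xrcc6 -5.58; 4.35e-05). For these 5 lists the estimated correlation gave 0.342, or 0.344 for the splicing regulators. Heat-shock chaperone genes split 18 up (Cct3 2.07, Cct2 1.65) and 6 down (Hspb8 -7.67, Hspa9 -2.25) of 34, with adjusted p = 0.178. Of 34 p53 targets, which radiation can induce, 17 rose and 11 fell: Bbc3 rose by 2.66 and Pmaip1 by 4.65, and Phlda3 (-3.04) and Fas (-4.10) fell (adjusted p = 0.636). Immediate early genes rose in 18 of 19 cases (Ier2 4.38, Dusp2 6.70; 7.77e-05, 0.342 with an estimated correlation), unfolded-protein response genes in 15 of 27 with 4 falls (0.0398, 0.342), apoptosis genes in 10 of 19 with 4 falls (0.222), interferon genes in 6 of 28 with 2 falls (0.434), and Notch and T-cell leukemia genes in 13 of 28 with 7 falls (Lyl1 5.68, Notch3 -4.74; 0.141). Hsf2 did not pass (-0.66 ± 0.34, adjusted p = 0.111), but did without the library labelled irradiated knockout replicate 2 (-1.12, adjusted p = 0.0044), and Hspa4 did not (0.37 ± 0.16, adjusted p = 0.0623), though it passed with limma-voom (0.38, adjusted p = 0.0483) and library size only (1.51, adjusted p = 2.5e-05). Of 12 genes that flank Hsf2, 2 rose and 6 fell, which flips to 6 and 5 with library size only (adjusted p = 0.141), and of 3 sex-linked genes 1 rose. Xist, on the sex-linked list, had 7806 counts in irradiated knockout replicate 2 and at most 123 in any other library.

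Adjusted for genotype, 8074 of 11754 genes differed by radiation label, 4222 higher and 3852 lower. With library size only the split was 6751 and 2412, and the median of all genes moved from 0.155 to 1.29. Within the libraries labelled wild type 6808 genes differed (3350 higher, 3458 lower; 5622 and 2088 with library size only), and Hsf2 did not pass (-1.07 ± 0.45, adjusted p = 0.0766). Under the knockout label 6544 differed (3253 and 3291; 6077 and 2027 with library size only), and 4232 did without the library labelled unirradiated knockout replicate 2. Mpo rose by 12.27 and 12.81 in the 2 arms and Cidea fell, at -12.31 and -13.78. Of the genes called in both arms 2602 were higher in each, 2885 lower in each and 8 opposite. Since the labels give no unirradiated library without fat genes, radiation and tissue content cannot be parted in these counts.

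The remaining question is what differs between the knockout and wild-type labels within each radiation label. Among libraries labelled unirradiated, Hsf1 did not pass at the level of all genes (-7.89 ± 0.73, adjusted p = 0.0786; 0.352 ± 0.277 against 76.3 ± 44.2 CPM, n = 2 each), and Hsf2 was at -0.34 ± 0.45. The smallest p-values after Hsf1 were those of Ier5 (1.72, adjusted p = 0.762) and Elovl3 (2.66, adjusted p = 1.0). Hspb8 (61.1 ± 0.873 against 169 ± 9.47 CPM) and Hsp90ab1 (-1.20 ± 0.31) lay lower in 2 of 2 libraries without passing. Of all tested genes 37.1% had replicates apart in this comparison, where 33.3% are apart by chance. The 34 chaperone genes had a median log2 fold change of -0.45 and camera called them lower (adjusted p = 7.1e-10, but 0.977 with an estimated correlation). By edgeR 0 genes passed and 211 had an unadjusted p under 0.05, while DESeq2 called 4 and limma-voom 0. Without the library labelled unirradiated wild type replicate 1, edgeR called 1, Hsf1 (adjusted p = 0.0472).

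Among libraries labelled irradiated, Hsf1 had the smallest p again (-8.71 ± 0.76, adjusted p = 0.0513). Sex-linked genes set irradiated knockout replicate 2 apart (7806 counts of Xist, 37 of Eif2s3y), so sex is mixed with the knockout label here. Pvrl1 (2.99 ± 0.30; 148 ± 35.7 against 18.6 ± 4.45 CPM) and Megf9 (2.04 ± 0.22) each had adjusted p = 0.0697, and Bcam (-2.50) and Sec31a (1.81) 0.0732. Red-cell genes were lower under the knockout label without passing: Hbb-b2 at -4.01 ± 0.48 (adjusted p = 0.0738) and Car2 at 1430 ± 261 against 4980 ± 1230 CPM (adjusted p = 0.105). Of 32 erythroid genes 15 fell when adjusted over the list alone (camera adjusted p = 4.06e-10, 0.699 with an estimated correlation), and the list took 0.803 and 0.865% of counts in the 2 libraries labelled knockout against 2.99 and 7.35% in the 2 labelled wild type. Neutrophil genes took more in the same libraries, at 2.73 and 3.82% of counts under the knockout label against 1.53 and 2.37% (camera adjusted p = 0.00401, 0.699 with an estimated correlation). In this comparison 0 genes passed by edgeR, 1898 had an unadjusted p under 0.05, DESeq2 called 493 and limma-voom 0. Leaving out the library labelled irradiated wild type replicate 2 gave 533, with Hsf1 (adjusted p = 0.00689), Pvrl1 (0.0127), Megf9 (0.0138), Bcam (0.00716), Sec31a (0.0133), Hbb-b2 (0.0163) and Car2 (0.00661) among them, and leaving out irradiated knockout replicate 1 gave 3. Fitted without the libraries labelled unirradiated, edgeR called 1, Hsf1 (adjusted p = 0.0481).

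Adjusted for radiation over all 8 libraries, Hsf1 was the 1 gene called by edgeR; DESeq2 called 24 and limma-voom 1, and without the library labelled irradiated wild type replicate 2 edgeR called 2. For the interaction of genotype and radiation labels 0 genes passed by edgeR and 1006 had an unadjusted p under 0.05, with DESeq2 at 59 and limma-voom at 0. Pvrl1 (3.22 ± 0.41), Sec31a (2.10 ± 0.29) and Bcam (-2.51 ± 0.37) led it, each with adjusted p = 0.539. Without irradiated wild type replicate 2 edgeR called 91 for the interaction and without irradiated knockout replicate 1 it called 1. In simulated data of this depth and spread, edgeR recovered 26% of genes changed 4-fold within 1 radiation label and 64% adjusted for radiation. By these shares smaller changes would mostly be missed. Each simulated gene had its mean level over all 8 libraries, with no difference by radiation label. The shares are therefore only a rough guide to the real libraries of 1 radiation label.

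Across species, 0 genes called lower in sgHsf2 cells were also called lower under the mouse knockout label, since 1 mouse gene was called by edgeR at all. At an unadjusted p under 0.01 in both, JUN, HSP90AB1, RAB11FIP4, RAB6B and RBM38 were lower in sgHsf2 cells and in the libraries labelled unirradiated knockout, 5 against 1.7 expected (Fisher exact p = 0.0188), which does not pass over the 12 tests made (adjusted p = 0.226). The other overlaps at that threshold were near the number expected: 3 genes higher in both against 2.6 for the unirradiated label, 60 higher against 60 and 30 lower against 28 for the irradiated label, and 10 higher against 9.1 and 7 lower against 5.1 adjusted for radiation.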

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

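The tests in this part on HSF1, on the chaperone list, on the mouse libraries and on splits of the libraries were chosen after the result was seen; those on the neighbours of HSF2 and HSPH1 were written before it.

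Chaperone and megakaryocyte genes went opposite ways in the edited K562 lines, so the difference was tested directly. The difference of sgHsp110 from sgHsf2 cells had a camera adjusted p = 8.04e-10 for the heat-shock list (median log2 fold change 0.30, 32 of 42 genes higher) and 1.48e-05 for the megakaryocyte list (median -0.89, 11 of 16 lower). Over the other list tests the adjusted p ran from 5.69e-09 to 0.29 for the first and from 3.73e-06 to 0.138 for the second, with the highest value from the estimated correlation. The difference may be a trait of the cell populations, which was not tested.

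For the interaction of genotype and radiation labels camera gave adjusted p = 0.0372 for the spliceosome, 0.012 for interferon genes, 2.13e-06 for erythroid genes, 0.0229 for neutrophil genes, 0.0105 for stromal genes and 0.012 for the added adipocyte list; neutrophil genes had a positive interaction and the other lists a negative one. With an estimated correlation these were 0.949, 0.949, 0.878, 0.878, 0.878 and 0.878, fry gave 0.521 to 0.921, and the replicate block 1.08e-06 to 0.0521. Single genes past the threshold numbered 0 by edgeR (1006 at an unadjusted p under 0.05), 59 by DESeq2 and 0 by limma-voom. Since the radiation labels also part tissue markers, an interaction may reflect how much of each cell type the 2 libraries of a group hold.

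HSF2 and HSPH1 both lay lower in sgHsf2 cells, and a loss of their chromosome regions is 1 candidate reason. The 48 tested genes within 5 Mb of HSF2 had a median log2 fold change of -0.08 (95% bootstrap interval -0.19 to 0.01) and the 55 within 5 Mb of HSPH1 -0.11 (-0.17 to -0.04), both above the -0.4 set for a lost copy. Less HSF1 transcript is another, and its log2 fold change was 0.02. That value covers RNA only, so less HSF1 protein or activity was not tested. HSPH1 could also fall as part of the chaperones as a group, which stays open: the list had adjusted p = 0.567 with an estimated correlation, and 5.92e-05 to 0.00456 in the other tests. An effect of HSF2 on HSPH1 is a hypothesis that rescue with HSF2 could test.

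Hsf1 rather than Hsf2 was missing under the mouse knockout label. Reads lost between transcript lines may hide a gene. All Hsf1 counts lie in the same transcript line, and the other Hsf1 lines hold 0 counts in every library. The lowest Hsf1 count under the wild-type label was 588, so that line is counted. Reads lost from the other lines were not tested. Libraries of another mouse line, such as an Hsf1 knockout, are a second candidate; Hsf2 had a log2 fold change of 0.07 ± 0.34 adjusted for radiation, which leaves this open, since an Hsf2 knockout allele could keep a counted transcript. An Hsf2 knockout that also lacks Hsf1 is another. Genotyping of the mice, or the exons covered by reads of both genes, would part these.

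Fat and muscle genes marked the libraries labelled unirradiated and blood genes those labelled irradiated. Were these marrow libraries with a minor share of adipose RNA, neutrophil genes should persist. The first test, on the share of counts, gave 19.7%, between the limits of 10 and 50 written for it. The test that replaced it after that result gave 0.4% as the median over 20 genes. These were chosen for at least 100 counts in every library labelled irradiated and so through the group where they are high. Cebpa (1918%), Hp (257%) and Mmp9 (33.8%) lay far above that median. Whether their RNA came from neutrophils was not tested, so they do not show that neutrophil RNA persisted. Of 7 blood-cell lists 5 were higher under the irradiated label, with a bound set after the data were seen and with 0 of these camera calls left under an estimated correlation; this restates the pattern, so a tissue other than marrow stays a hypothesis. A response to radiation could not be tested: the lowest adipocyte share among libraries labelled unirradiated was 14.9%, which restates the pattern. The design holds no library that could decide it. Yet a response to radiation would not act in those libraries, where the share was 14.9 to 17.8%. As the labelled sort would remove adipocytes, these shares argue against libraries of only the sorted cells under that label. The adipocyte list has 23 tested genes, among them Ucp1 and Cidea. Of these, 2 are also in another list and 13 reach 1 CPM under the irradiated label. A sort for lineage-negative Kit-positive cells would remove adipocytes. The counts do not show that sort, with Kit at 0 in each library labelled unirradiated and at 0 to 12 in those labelled irradiated. Genes with several transcript lines have lower counts in this table, and this was not tested for Kit. Its counts alone therefore do not argue against the sort.

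Splits of the libraries were counted beside the called genes. For K562 the 10 splits of 3 against 3 are too few for a share under 0.05; the real split gave 7188, 8124 and 9315 genes and the highest other split 0 in each comparison. Adjusted for radiation, 1 of 34 splits, the real one, gave the 1 gene of the knockout label, and 1 of 34 gave the 8074 of the radiation label adjusted for genotype, with 0 as the highest other for both. These splits do not keep the other label balanced and were chosen after the result was seen, so they do not exclude chance.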

How the results depend on the processing

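The tests with library size only and with genes of 1 line were chosen after the result was seen, and the others before. In K562 the counts of called genes stayed within 5729 to 6701 (sgHsf2), 6080 to 8222 (sgHsp110) and 7984 to 9354 (the lines against each other) when any 1 library was left out, and a minimum of 2-fold left 1319, 1070 and 1768. For the knockout label without radiation edgeR called 0 genes, with 51 unfiltered, 1 by library size only, 4 by DESeq2, 0 by limma-voom, 5 in a fit of only the groups compared and 1 without wild type replicate 1 (range 0 to 1). Under the irradiated label the 0 became 870 unfiltered, 2 by upper-quartile scaling, 1 by library size only, 493 by DESeq2, 0 by limma-voom, 1 with only the groups compared, and 533 and 3 without wild type replicate 2 or knockout replicate 1 (range 0 to 533). The interaction went from 0 to 253 unfiltered, 59 by DESeq2, 0 by limma-voom, and 91 and 1 without the same libraries (range 0 to 91). Adjusted for radiation the 1 gene became 327 unfiltered, 24 by DESeq2, 0 among genes with 1 line, since Hsf1 has several, and 2 without irradiated wild type replicate 2 (range 1 to 2). Genes with 1 line gave 3732, 3623 and 4447 for radiation under the wild-type label, the knockout label and adjusted for genotype, where fewer genes were tested; leaving out libraries gave 4595 to 6571, 4232 to 5893 (4232 without unirradiated knockout replicate 2) and 7519 to 8304. Libraries of the same replicate number did not share residuals throughout (correlations -0.447 to 0.302 over 9 K562 pairs and -0.269 to -0.063 over 12 mouse pairs). With 2 mouse libraries per group the residuals mirror each other, so each mouse value occurs for both numbers. Crossed mouse pairs have the opposite sign, up to 0.269, and were not fitted as a block. As a block, replicate number gave 6652 (sgHsf2), 7592 (sgHsp110) and 8865 (lines against each other) genes in K562. In mouse it gave 0, 0 and 1 for the knockout label (unirradiated, irradiated, adjusted) and 0 for the interaction. For radiation it gave 6198, 6045 and 7818 (wild type, knockout, adjusted). Of 101 list calls 0 held with an estimated correlation and 100 list calls were made with the block. At an adjusted p of 0.01 the shared K562 changes went from 2593 to 1428 and the shared radiation changes from 5487 to 3582, and the overlap of mouse (irradiated label) and K562 went from 0 to 90 at an unadjusted p under 0.01, 60 higher and 30 lower where 60 and 28 are expected. Among 3218 recomputed values of named genes 3095 were the same, 70 weaker, 52 stronger and 1 reversed. With the 2-fold minimum set aside, 20 values were weaker and 4 genes had a value that lost its call. The reversed value was Hp by radiation label, -1.04 in the report and 0.10 (adjusted p = 0.615) with library size only. For the other moves the cause was not tested.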

Other observations

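The tests in this part on shifted windows were written before the result was seen, except that splitting them by line came after it.

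SYK, a kinase of immune receptors, fell to under 0.1 CPM in both edited K562 lines, from 5.41 ± 0.674 CPM in parental cells (n = 3). MBNL3, a splicing regulator, fell from 1.21 ± 0.0695 to 0.154 ± 0.0271 in sgHsf2 and 0.16 ± 0.0256 in sgHsp110 cells. ZNF521 and ENAH rose in sgHsp110 cells and lay lowest in sgHsf2 cells, at 0.126 ± 0.0574 and 5.71 ± 0.617 CPM. CD44 and SCIN went the other way, at 0.71 ± 0.187 and 0.285 ± 0.097 in sgHsp110 cells against 19.3 ± 4.09 and 12.4 ± 0.496 in sgHsf2 cells. Large changes that part the edited lines in both directions may mark cell populations grown from few cells, and other guides and other clones would test it.

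Mouse libraries differ in sex-linked genes as well. The library labelled irradiated knockout replicate 2 has 7806 counts of Xist and 37 of Eif2s3y, and the other 7 have 811 to 2129 of Eif2s3y and at most 123 of Xist. A comparison that uses this library, such as the knockout label among irradiated libraries or the interaction, mixes sex with the labels. Without it the comparison adjusted for radiation called 1 gene, Hsf1, as it did with all 8 libraries, so that call does not rest on this library.

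Neighbouring genes shifted together in sgHsf2 cells. Of 295 windows of 10 Mb, 14 had a median log2 fold change past 0.25 in size, against at most 2 in 1000 shuffles; 11 lie on chromosome 11, 1 each on chromosomes 5 (0.27) and 12 (0.42), and 1 is the mitochondrial genome, which is no copy of a chromosome. In sgHsp110 cells 4 windows did, no more than the highest shuffle (4), among them chromosome 5 from 60 to 70 Mb (-0.47). Taken over both lines the prediction was not settled. An extra copy of chromosome 11 in sgHsf2 cells is a hypothesis: the median fold of 1.32 on it could come from 4 copies in place of 3, and sequencing of DNA would test it. Such a gain may have preceded the edit or followed it.

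Erythroid genes and JUN give 2 more hypotheses. Erythroid genes took 0.6146 to 0.6524% of parental counts and 0.4674 to 0.4735% of sgHsf2 counts, and HSF2 may sustain part of the erythroid program of K562 cells. Camera with an estimated correlation did not call that list (adjusted p = 0.329). It kept none of the list calls, so it decides neither for nor against the hypothesis. A trait of the sgHsf2 cell population was not excluded. Hemoglobin staining after HSF2 is put back would test it. JUN fell in both edited lines, which may reflect less HSPH1, a change the lines share, and HSPH1 put back into each would test that.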
